A study of Mus musculus with 12 samples.

How the data were processed

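RNA of 6 spontaneous HCC and 6 normal livers of untreated 2-year-old B6C3F1 mice was measured on 12 single-colour Affymetrix arrays, 1 per animal. Per the labels, total RNA was extracted with TRIzol and a column with DNase, and 1 microgram was labelled with biotin by one-cycle cDNA synthesis. The intensity values, as deposited, were linear signals for 45101 probe sets, between 0.104 and 82665.9, scaled so that the 2% trimmed mean of each array was 500.0. The method that summarised probes into probe sets is not given in the sources used here. The labels give no sex, batch or pairing of animals. Both groups are numbered 1 to 6, and the same-number arrays had correlations of deviations from -0.0147 to 0.0777, so the numbers were not taken as pairs.

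The arrays did not share a median. By a rule set beforehand, log2(intensity + 16) was therefore quantile normalized, which had been listed as the alternative for arrays that share one. The 64 Affymetrix control probe sets were left out of the gene tests. Of the other 45037 probe sets, 34945 named 1 gene, 932 named several and 9160 had no gene symbol in the annotation used here, and each of 18193 genes was represented by its brightest probe set. Chromosomes were taken from the GRCm38.p6 annotation by gene ID.

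HCC and normal liver were compared with limma (version 3.58.1, lmFit and eBayes, in R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 40 gene lists held 781 entries, of which 702 were matched by symbol and 3 by synonym, and 76 were not measured here by a probe set of 1 gene. limma's camera tested the 39 lists with at least 5 measured members, with a preset correlation of 0.01. Its calls were set beside a correlation estimated for each list, fry, and an exact permutation of list means that was added after the data were seen. Adjustment over the list alone used the members of 1 list as the family. Spread between animals was compared by an exact permutation test of the 12 values. Tables and figures also used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

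The named genes were chosen by a rule. It took the 10 largest rises and 10 largest falls with an adjusted p under 0.05 and complete separation of the groups whose higher mean lay above the median probe set. From each list it took up to 3 members with the largest difference past the test, or the member with the smallest p where none passed. It also took the X- and Y-linked genes, the control probe sets, and Afp, Gpc3, Glul, Axin2, Mki67, Cdkn1a and Hamp. The lists, the tests, this rule and most other settings were fixed before the data were examined.

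Tested on simulated data, the gene test recovered 2%, 56%, 86% and 98% of 50 genes changed by 0.5, 1, 2 and 4 on the log2 scale and called 10 of 17993 unchanged genes. camera called 3 of 3 shifted lists and 0 unshifted ones. Genes were drawn independently, so this does not test camera on lists whose members are correlated. The correlation estimated from the arrays was 0.854 in the list of Wnt targets and 0.798 in that of periportal genes. A simulated spread ratio of 1.5 was found as 1.501, and 7% of 100 simulations without a difference had p under 0.05. The simulations of spread also drew genes independently, and those without a difference used only a part of the genes.

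Results were recomputed with other pseudocounts, a filter on dim genes, the mean of all probe sets of a gene, a trended and robust variance model, array weights, the replicate number as a block, leaving out each array, an exact Wilcoxon test, a stricter threshold, counting every probe set, and other measures of spread. The deposited scaling, median centring, the Y-linked level as a covariate, and the arrays with or without Y-linked signal alone were added after the data were seen. The 10092 probe sets without a single gene name were not used in the comparisons of genes.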

Results

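Gene expression was measured in 12 livers of B6C3F1 mice, the first-generation cross of C57BL/6 and C3H used in the bioassays of the National Toxicology Program. The mice were 2 years old and had received no treatment. One group held 6 hepatocellular carcinomas (HCC) that had arisen spontaneously and the other held 6 normal livers, each measured on 1 single-colour Affymetrix array. The number of arrays limits the precision of each value. The deposited intensities had a 2% trimmed mean of 500.0 on every array, and 14.2% to 18.1% of probe sets lay under an intensity of 16. Control probe sets at the 3' and 5' ends of Gapdh, which report on RNA integrity, gave a 3'/5' ratio of 0.736 ± 0.0385 in HCC and 0.745 ± 0.0360 in normal liver (SD, n = 6 each, exact permutation p = 0.671). The same ratio for beta-actin was 1.49 ± 0.107 in HCC and 1.64 ± 0.113 in normal liver (SD, n = 6 each), with an exact permutation p of 0.0433 that became 0.303 after Benjamini-Hochberg adjustment over 7 measures.

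The X-linked transcript Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty split both groups in the same proportion. Normal 1, normal 3, HCC 1 and HCC 4 had Xist at log2 levels from 11.79 to 12.70 and a mean of the 3 Y-linked genes from 4.17 to 4.85. The other 4 normal livers and 4 HCC had Xist between 5.12 and 7.56 and the Y-linked mean between 8.96 and 9.78. The labels give no sex, and none of the 4 genes differed between HCC and normal liver (limma, 0 of 4 also when adjusted over the list alone; log2 differences of 0.19 for Xist, -0.16 for Eif2s3y, -0.03 for Kdm5d and 0.36 for Uty, adjusted p from 0.875 to 0.991). The sign for Kdm5d turned positive with the deposited scaling and with median centring, and that for Eif2s3y with the mean of all probe sets of a gene.

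The first comparison asked which genes differed between spontaneous HCC and normal liver. Alpha-fetoprotein (Afp), the main plasma protein of the fetal liver, rose most, by 8.26 ± 0.45 on the log2 scale (SE, limma adjusted p = 5.67e-07), from 5.72 ± 0.81 in normal liver to 13.97 ± 0.88 in HCC (SD, n = 6 each). The oncofetal proteoglycan glypican 3 (Gpc3) rose by 5.38 ± 0.48, the tetraspanin Tspan8 by 7.05 ± 0.53, and Ly6d by 5.55 ± 0.51. The other genes among the 10 largest rises were the X-linked Bex1 at 7.28, the hydroxysteroid dehydrogenase Akr1c18 at 7.27, the trefoil factor Tff3 at 6.02, the protease inhibitors Slpi at 5.34 and Spink1 at 5.06, and carboxypeptidase E (Cpe) at 5.20. These 10 had adjusted p-values from 1.9e-07 to 0.00456, and in each of them all 6 HCC lay above all 6 normal livers. Cpe and Spink1 varied most among the tumours, with SDs of 2.57 and 2.40.

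The largest falls included genes of iron, bile acid, lipid and drug metabolism. Hepcidin (Hamp), the hormone that limits iron uptake, fell by 4.71 ± 0.72 on the log2 scale, and its paralogue Hamp2 fell by 5.65 ± 0.69. Cyp8b1, the sterol 12-alpha-hydroxylase of bile acid synthesis, fell by 5.20 ± 0.40, Cyp2c54 by 4.83 ± 0.55, and Cyp2f2 by 4.50 ± 1.03. The sulfotransferase Sult2a8 fell by 5.76, the fatty acid elongase Elovl3 by 5.23, the carboxylesterase Ces1e by 4.80 and dopachrome tautomerase (Dct) by 4.71. The major urinary protein gene Mup10 fell by 6.52, a value that is uncertain because that family holds near-identical copies, as do Hamp and Hamp2. In 4 of the 6 HCC Mup10 lay between 4.23 and 4.65, close to the floor of 4 that the pseudocount sets, so the size and rank of its fall are not well measured. Normal livers were also near that floor for some of the largest rises, down to 4.27 for Afp, 4.29 for Tspan8, 4.54 for Spink1, 4.71 for Akr1c18 and 4.93 for Cpe, so the sizes of these rises and their order are limited in the same way. Adjusted p-values of these 10 genes ran from 1.17e-05 to 0.0132.

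**Figure D1:**
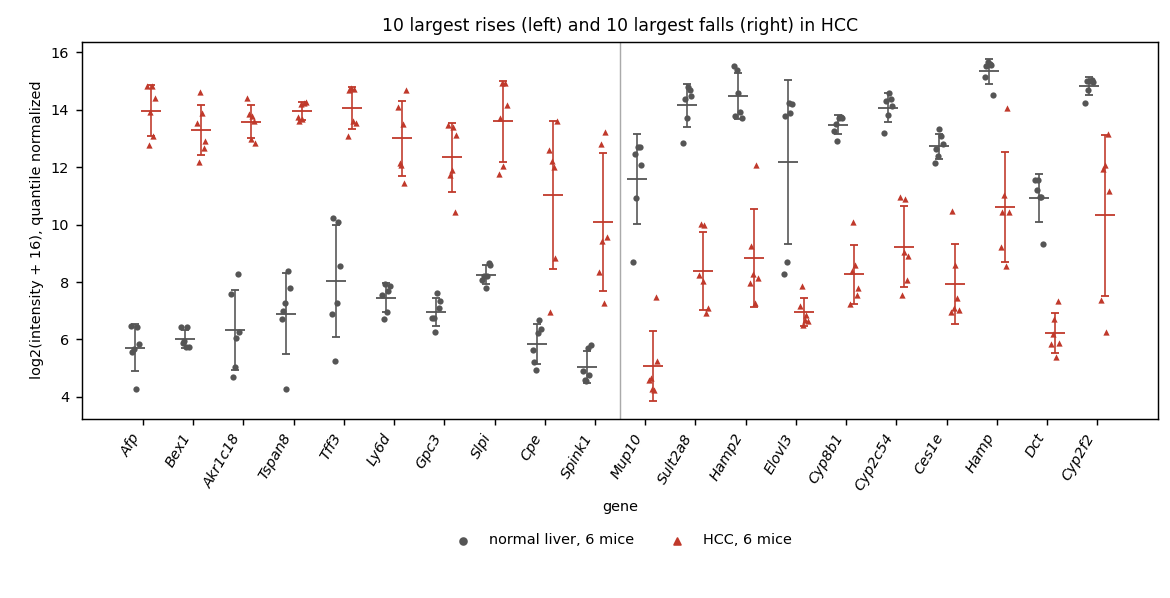
Log2(intensity + 16) after quantile normalization for the 10 genes with the largest rise and the 10 with the largest fall, 1 point per mouse, with horizontal marks for group means and bars for the SD (n = 6 each). In every gene the 6 HCC lie on 1 side of the 6 normal livers; Elovl3 spreads most among normal livers, with an SD of 2.87.

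Across 18193 genes, limma called 1179 higher and 1319 lower in HCC at a Benjamini-Hochberg adjusted p under 0.05, of which 620 and 574 differed by at least 1 on the log2 scale. All 6 HCC lay above all 6 normal livers in 773 genes and below them in 818, which is 8.75% of genes against 0.216% from chance for 6 against 6. The median log2 difference over all genes was -0.04. With the deposited scaling the balance turned, with 1403 genes higher and 1087 lower. Within the 4 HCC and 4 normal livers with Y-linked signal, 575 genes were higher and 564 lower; within the 2 and 2 without it, 40 were higher and 36 lower, from fewer arrays. Of 104 named genes past the test, 84 stayed past it with each array left out in turn. Among the arrays with Y-linked signal all 104 kept their direction, but 44 no longer passed. In the arrays without it 86 no longer passed. Both sets hold fewer arrays. In 6 of the 104 another probe set of the gene differed in sign, without passing the test: Cpe (-0.77), Hamp2 (0.18), Cyp27a1 (0.40), Lats2 (down to -0.52), Impact (-0.21) and Il1r1 (-0.19).

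Genes of 40 lists fixed before the data were examined are described next, each with the number of members past the test over all genes and the number adjusted over the list alone. limma's camera compared each list with all other genes, with a preset correlation between members, and called 11 lists higher and 11 lower in HCC. With a correlation estimated from the arrays, 1 of the 11 higher and 2 of the 11 lower lists held. An exact permutation of the mean of each list over the 924 assignments of the 12 arrays to 6 and 6 kept 17 of the 22 calls. The lists not kept were periportal, male-biased, cholesterol synthesis, acute phase and extracellular matrix. Other ways of splitting the 12 arrays also gave list calls, in up to 18 lists one way. limma's fry, which asks whether the members of a list move one way, lost periportal, cholesterol synthesis, glycolysis and extracellular matrix. The p-values of single genes and of permutations measure the spread between animals, while those of camera with a preset correlation compare member genes with other genes.

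In the list of fetal and oncofetal liver genes 8 of 18 measured members rose and none fell (9 higher and 1 lower adjusted over the list alone), led by Afp, Tspan8 and Ly6d. This list held with an estimated correlation (camera adjusted p = 0.0215). Of 34 cell cycle and mitosis genes, 23 rose (28 higher and 1 lower adjusted over the list alone), among them the apoptosis inhibitor and mitotic protein Birc5 by 2.95, the ubiquitin-conjugating enzyme Ube2c by 2.81, the mitotic kinase Cdk1 by 2.60 and the proliferation marker Mki67 by 2.41 (adjusted p = 0.0576 with an estimated correlation). Among the tumours HCC 5 had the lowest mean of this list, at 0.56 above normal, and the others lay between 1.26 and 1.69. Of 18 genes induced by MAPK-ERK signalling, 10 rose and none fell (12 higher adjusted over the list alone), with the ERK phosphatase Dusp5 up by 3.93 and Ier3 by 3.36 (adjusted p = 0.0507 with an estimated correlation). Dusp4, at 2.11, lost its call without any of 6 single arrays (adjusted p up to 0.066).

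In the list of immediate early and heat shock genes, which respond quickly to growth factors or stress, 7 of 16 rose and 9 did not pass the test (7 adjusted over the list alone), led by Egr1 at 3.06, Fos at 2.25 and Jun at 1.92 (adjusted p = 0.148 with an estimated correlation). Of 18 genes of ER stress and the amino acid response, 5 rose (5 adjusted over the list alone). The 3 largest were enzymes of serine and asparagine synthesis, Psat1 at 2.83, Asns at 2.52 and Phgdh at 2.30 (adjusted p = 0.303 with an estimated correlation). The interferon response list had 6 of 18 members higher (10 adjusted over the list alone), with the chemokine Cxcl9 at 2.22, Ifit2 at 1.87 and Usp18 at 1.76 (adjusted p = 0.4 with an estimated correlation). In the acute phase list 5 of 23 members rose and 2 fell (7 and 3 adjusted over the list alone), with lipocalin 2 (Lcn2) up by 4.73 and Serpina3n by 1.31. Its call was lost with an estimated correlation (adjusted p = 0.482), by exact permutation (adjusted p = 0.076) and without HCC 5 (camera adjusted p = 0.0769). Il1r1 of that list, at 1.95, lost its call without any of 8 single arrays (adjusted p up to 0.0897).

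The title of the study names human liver cancer as its point of comparison. Of 22 measured genes known to be higher in human liver cancer, 11 rose and 1 fell in the mouse tumours (11 and 1 adjusted over the list alone; adjusted p = 0.0761 with an estimated correlation). Afp, Tspan8 and Gpc3 led, and 8 of the 11 are also on the fetal or cell cycle lists. Of 25 genes known to be lower in human liver cancer, 10 fell and none rose (12 lower and 2 higher adjusted over the list alone; adjusted p = 0.174 with an estimated correlation), with Hamp at -4.71, the insulin-like growth factor carrier Igfals at -2.16 and the sinusoidal lectin Clec4g at -2.13.

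Several lists of metabolic genes were called lower, while glycolysis was called higher and lipogenesis was not called. Of 24 cytochrome P450 genes and regulators of drug metabolism, 11 fell and none rose (12 adjusted over the list alone), with Cyp2c54 at -4.83, Cyp2f2 at -4.50 and Cyp2c50 at -3.34, and this list held with an estimated correlation (adjusted p = 0.0215). The falls of Cyp2f2 and Cyp2c50 differed with Y-linked signal (limma interaction, adjusted p = 0.0248 and 0.00247). Cyp2f2 was at -2.92 with it and -7.64 without it, and Cyp2c50 at -4.500 and -1.02. HCC 1 and HCC 4, the only tumours without Y-linked signal, also had the highest means of Wnt targets and the lowest of periportal genes, described below. Cyp2f2 is itself on the periportal list. Dependence on Y-linked signal therefore cannot be told apart here from that state of these tumours. The list of gluconeogenesis and glycogen genes also held (adjusted p = 0.0215), and there 6 of 13 fell (7 adjusted over the list alone), among them glucose-6-phosphatase (G6pc) at -1.90, the glycogen-targeting subunit Ppp1r3b at -1.30 and the glucose-6-phosphate transporter Slc37a4 at -0.97. Urea cycle and amino acid catabolism had 15 of 28 members lower (21 adjusted over the list alone), including Cth at -1.55 (adjusted p = 0.228 with an estimated correlation). The 2 largest differences past the test in that list were Prodh at -1.83 and Kynu at -1.77, whose calls were each lost without any of 9 or more single arrays (adjusted p up to 0.0804 and 0.091). Bile acid synthesis and transport had 10 of 20 lower and 1 higher (13 and 1 adjusted over the list alone), with Cyp8b1, the rate-limiting Cyp7a1 at -3.41 and Cyp7b1 at -2.32 (adjusted p = 0.125 with an estimated correlation). In fatty acid oxidation 11 of 25 fell (15 adjusted over the list alone), including Cpt2 at -1.33 and Eci1 at -1.09 (adjusted p = 0.373 with an estimated correlation). Acaa1b, at -1.71, lost its call without any of 6 single arrays (adjusted p up to 0.0603).

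Iron handling had 3 of 13 members lower (6 adjusted over the list alone), Hamp2, Hamp and Hfe, the last at -0.71 (adjusted p = 0.174 with an estimated correlation). Hfe lost its call without either of 2 single arrays (adjusted p up to 0.0534). Cholesterol synthesis had 3 of 19 lower (6 adjusted over the list alone), Tm7sf2 at -1.09, Msmo1 at -0.83 and Hsd17b7 at -0.77. Its call was lost with an estimated correlation (adjusted p = 0.503) and by exact permutation (adjusted p = 0.0998), and that of Hsd17b7 without any of 4 single arrays (adjusted p up to 0.0573). Lipogenesis and lipid storage was not called (camera adjusted p = 0.134), with 4 of 26 higher and 6 lower (4 and 11 adjusted over the list alone). There the desaturase Scd2 rose by 4.81 and lipoprotein lipase (Lpl) by 4.10, while the lipogenic regulator Thrsp fell by 2.98. Glycolysis was called higher with 3 of 15 members up and 1 down (6 and 1 adjusted over the list alone; adjusted p = 0.482 with an estimated correlation). Aldolase A (Aldoa) was at 1.34 and pyruvate dehydrogenase kinase 1 (Pdk1) at -1.65, and muscle pyruvate kinase (Pkm), at 2.18, lost its call without any of 9 single arrays (adjusted p up to 0.0889). In HCC 6 the glycolysis mean was 1.47 above normal, against 0.12 to 0.47 in the other tumours.

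**Figure D2:**
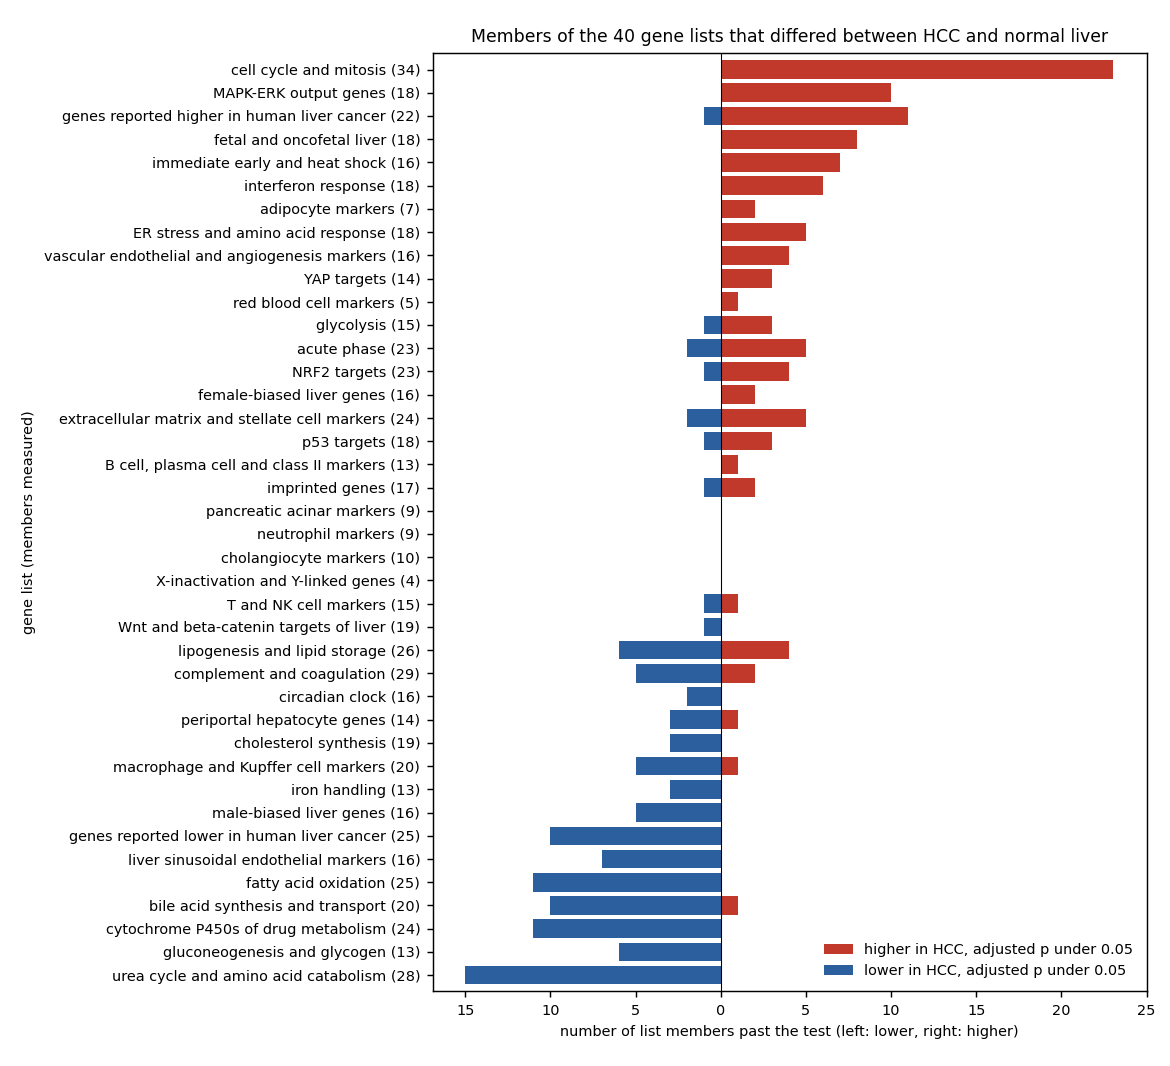
Number of members of each of the 40 gene lists that passed limma's test at a Benjamini-Hochberg adjusted p under 0.05, to the right for higher and to the left for lower in HCC, with the number of measured members in brackets. The longest bars are the 23 of 34 cell cycle genes on the right and the 15 of 28 genes of the urea cycle and amino acid catabolism on the left.

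Targets of Wnt and beta-catenin signalling, which normally mark hepatocytes around the central vein, moved in opposite directions in different tumours. The mean of 19 measured members relative to normal liver was 2.23 in HCC 1, 1.68 in HCC 4 and 0.44 in HCC 6, and -1.86 in HCC 2, -1.70 in HCC 3 and -1.24 in HCC 5, against an SD of 0.105 among normal livers. Glutamine synthetase (Glul), the classical target, was at log2 levels of 15.16, 15.10 and 14.62 in HCC 1, HCC 4 and HCC 6 and at 11.75, 11.40 and 12.03 in HCC 2, HCC 3 and HCC 5, and between 13.29 and 14.33 in the 6 normal livers. The feedback inhibitor Axin2 was at 11.76, 10.34 and 9.14 in the first 3 of these tumours and at 6.24, 5.06 and 6.36 in the others, with 8.24 ± 0.43 in normal liver. As a group the tumours did not differ from normal liver in Glul (-0.65 ± 0.67, SE, limma adjusted p = 0.577) or Axin2 (-0.09 ± 0.98, adjusted p = 0.966). The sign for Axin2 turned positive with the deposited scaling, and another probe set of Axin2 was at 0.92 without passing the test. The list was not called (median 0.06, mean -0.07, camera direction lower, adjusted p = 0.927), and 1 of its 19 members passed, Cyp27a1 at -1.29 (0 adjusted over the list alone; its call was lost without any of 9 single arrays, adjusted p up to 0.0615). The difference in list mean was 1.88 between the 2 HCC and 2 normal livers without Y-linked signal and -1.05 between the 4 and 4 with it.

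Periportal genes, which normally mark hepatocytes at the opposite end of the lobule, were lowest in the tumours with the highest Wnt target means. Their mean relative to normal liver was -3.002 in HCC 1 and -2.851 in HCC 4, -0.90 in HCC 6, -0.27 in HCC 2, 0.18 in HCC 3 and 0.44 in HCC 5. Of 14 measured members 3 fell and 1 rose (5 and 1 adjusted over the list alone). Cyp2f2 and Etnppl fell by 4.50 and 3.73, and the adhesion protein E-cadherin (Cdh1) rose by 4.67 ± 0.22 (SE, limma adjusted p = 1.56e-07), at log2 levels from 12.89 to 13.97 in the 6 HCC against 8.65 ± 0.33 in normal liver. The camera call of the list (adjusted p = 0.0403) was lost with an estimated correlation (adjusted p = 0.603), by exact permutation (adjusted p = 0.208), and without HCC 1 (0.152), HCC 4 (0.104), normal 1 (0.0577) or normal 3 (0.0639).

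Genes that differ between the sexes in normal mouse liver were compared between arrays with and without Y-linked signal. Among normal livers the mean of 16 male-biased genes was 3.08 higher with Y-linked signal than without, and among HCC 0.56 higher. For 16 female-biased genes the difference was -3.16 among normal livers and -0.82 among HCC. The difference was smaller in HCC for 13 of 16 male-biased and 12 of 16 female-biased members. Members chosen after their values were seen went the other way, such as Mup3 at 1.67 in normal liver and 2.56 in HCC, and Hao2 at -2.60 and -3.25. An exact permutation of group labels within the arrays with and without Y-linked signal gave p = 0.0238 for the difference of these differences in the male-biased list and p = 0.00476, the smallest it can give, in the female-biased list. Over the 40 lists the adjusted values were 0.159 and 0.0635, so neither passed. The same exact permutation p of 0.00476 came from the T and NK cell list and the B cell, plasma cell and class II list, and that of 0.0238 from the Wnt target and pancreatic acinar lists. Against all normal livers 5 of 16 male-biased genes fell (10 adjusted over the list alone), with Elovl3 at -5.23 (-7.06 with Y-linked signal and -1.57 without, limma interaction adjusted p = 0.00246) and Ugt2b1 at -2.49, and the camera call was lost with an estimated correlation (adjusted p = 0.47) and by exact permutation (adjusted p = 0.0622). Mup3 of that list, at -3.73, lost its call without any of 9 single arrays (adjusted p up to 0.0644). Of the female-biased genes 2 rose (2 adjusted over the list alone), Prom1 at 4.29 and Abcd2 at 1.43, the latter lost without any of 8 single arrays (adjusted p up to 0.075). The female-biased list was not called (median -0.30, mean 0.06, camera adjusted p = 0.64). Its difference in mean was -1.499 in the arrays without Y-linked signal and 0.85 in those with it.

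**Figure D3:**
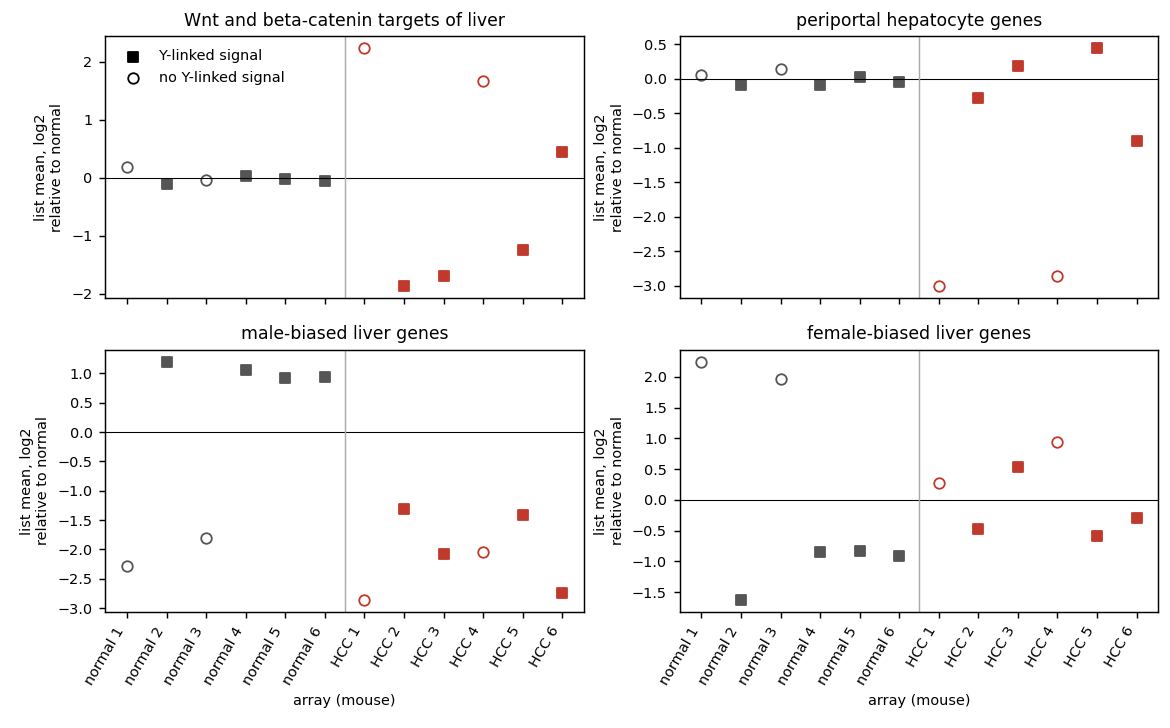
Mean log2 value of 4 gene lists in each mouse relative to the mean of the 6 normal livers (1 point per array; grey for normal liver, red for HCC; filled squares with Y-linked signal and open circles without it). Wnt targets range from -1.86 in HCC 2 to 2.23 in HCC 1, while the 6 normal livers lie between -0.11 and 0.19.

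Of 16 sinusoidal endothelial markers 7 fell and none rose (7 adjusted over the list alone), with Clec4g at -2.13, Ehd3 at -1.96 and the Wnt amplifier Rspo3 at -1.69 (adjusted p = 0.447 with an estimated correlation). Of 16 vascular endothelial and angiogenesis markers 4 rose and none fell (9 adjusted over the list alone), with Esm1 at 3.81, Cd34 at 2.38 and Aplnr at 2.21 (adjusted p = 0.373 with an estimated correlation). Relative to normal liver, the vascular mean exceeded the sinusoidal mean in all 6 HCC, by 1.97 ± 0.99 on average (SD, n = 6, exact sign-flip permutation p = 0.0312, the smallest it can give). In each HCC the vascular mean lay above normal and the sinusoidal mean below it, so that p was bound to be the smallest and adds no support. It was not among the main tests fixed beforehand. The macrophage list was not called (median 0.10, mean -0.003, camera adjusted p = 0.9), yet 5 of 20 members fell and 1 rose (6 and 1 adjusted over the list alone). The resident Kupffer cell markers Clec4f and Timd4 were at -2.36 and -2.11, and Cd14 was at 3.21. Extracellular matrix and stellate cell markers had 5 of 24 higher and 2 lower (6 and 2 adjusted over the list alone), with the basement membrane collagen Col4a1 at 2.26 and the stellate cell enzyme Lrat at -2.52. Col1a1, at 3.27, lost its call without any of 8 single arrays (adjusted p up to 0.0831). That list's call was lost with an estimated correlation (adjusted p = 0.634), by exact permutation (adjusted p = 0.476) and without HCC 6 (camera adjusted p = 0.45), where the list mean was 3.14 above normal against -0.87 to 0.61 in the other tumours. Without Y-linked signal its mean was -0.16.

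The remaining lists were not called by camera. T and NK cell markers had 1 of 15 higher and 1 lower (1 and 1 adjusted over the list alone; adjusted p = 0.137), Ccl5 at 1.38 and Cd5 at -0.68. The T and NK cell list mean was 0.63 with Y-linked signal and -0.17 without it, and that of B cell, plasma cell and class II markers 0.78 and -0.63. B cell, plasma cell and class II markers had 1 of 13 higher, Itgax at 2.01 (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0952). The calls of Ccl5 and Itgax were lost without any of 3 arrays and without 1 array (adjusted p up to 0.0635 and 0.0528). No member passed, over all genes or adjusted over the list alone, among 9 neutrophil markers (adjusted p = 0.196; S100a9 at 0.97), 10 cholangiocyte markers (adjusted p = 0.267; Cldn7 at 1.59) and 9 pancreatic acinar markers (adjusted p = 0.794; Prss2 at -0.98). Red blood cell markers had 1 of 5 higher, Slc4a1 at 1.31 (1 adjusted over the list alone; adjusted p = 0.226). Adipocyte markers had 2 of 7 higher, Fabp4 at 2.46 and Cidec at 1.83 (2 adjusted over the list alone; adjusted p = 0.205). YAP targets had 3 of 14 higher (3 adjusted over the list alone; adjusted p = 0.0754), with Ajuba at 1.49, Crim1 at 0.94 and Lats2 at 0.57, the last lost without any of 5 single arrays (adjusted p up to 0.0626).

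Among p53 targets 3 of 18 were higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.0501). The list mean lay above that of normal liver in 6 of 6 HCC and passed the exact permutation (adjusted p = 0.0113) and fry (adjusted p = 0.0353), but camera did not call it (adjusted p = 0.373 with an estimated correlation). Its members past the test included the antiproliferative gene Btg2 at 2.77, Phlda3 at 1.42 and Ei24 at -0.90. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 0.93 ± 0.55 (SE, limma adjusted p = 0.297). NRF2 targets had 4 of 23 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.051), with the carbonyl reductase Cbr3 at 2.68 and malic enzyme (Me1) at -1.98, while Abcc4, at 2.15, lost its call without any of 7 single arrays (adjusted p up to 0.0677). Complement and coagulation had 2 of 29 higher and 5 lower (4 and 6 adjusted over the list alone; adjusted p = 0.741), with the mannose-binding lectins Mbl1 at -1.22 and Mbl2 at -0.90. Klkb1 of that list, at -0.90, lost its call without any of 10 single arrays (adjusted p up to 0.0772). The circadian clock list had 2 of 16 lower (2 adjusted over the list alone; adjusted p = 0.508), Hlf at -1.69 and Nfil3 at -0.98, the latter lost without any of 7 single arrays (adjusted p up to 0.077). Imprinted genes had 2 of 17 higher and 1 lower (2 and 1 adjusted over the list alone; adjusted p = 0.137). The growth factor receptor adaptor Grb10 was at 1.61, Impact at 0.80 and Ndn at -1.52, and the last 2 lost their calls without 2 arrays in turn and without 1 array (adjusted p up to 0.0535 and 0.0524).

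The second comparison asked whether tumours differed more from each other than normal livers did. The root mean square log2 difference of an array from the mean of the other 5 of its group, over 18193 genes, was 0.669 ± 0.0395 in HCC and 0.560 ± 0.0184 in normal liver (SD, n = 6 each). The difference of 0.109, a ratio of 1.19, had an exact permutation p of 0.00216, two-sided, the smallest that 6 against 6 can give, and all 6 HCC (0.636 to 0.738) lay above all 6 normal livers (0.536 to 0.588). The permuted values are not fully independent, because arrays of a group share its mean, so this p is approximate. The SD between mice was higher in HCC for 64.7% of genes, with medians of 0.449 in HCC and 0.335 in normal liver. Pearson correlations across genes between arrays, in which genes are not independent replicates, had medians of 0.956 among normal livers, 0.936 among HCC and 0.919 between the groups.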

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

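The tests of the Wnt target list and of the share of hepatocytes, and the use of Y-linked signal, were chosen only after the results were seen. For the tests of low values and of gene clusters on chromosome 4, the margin of error required was set after their values were seen. Of 320 groups of 6 arrays examined, 21 had an array far from the other 5 by Dixon's criterion, where chance gives about 1 in 20, or 16.

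The Wnt target list lay above normal liver in HCC 1, HCC 4 and HCC 6 and below it in HCC 2, HCC 3 and HCC 5. Quantile normalization had already evened out the scaling of the arrays, so a test of scaling decides little here. All 6 tumours lay outside the middle 95% of 10000 random lists of like level, although HCC 6, at 0.441, was close to the bound of 0.388. The list was chosen after its means were seen, so a place outside that range was likely beforehand. Normal tissue mixed into the tumours would keep members inside the normal range. Of 19 members, 18 and 17 lay above it in HCC 1 and HCC 4, and 17, 16 and 15 below it in HCC 2, HCC 3 and HCC 5. HCC 6 had 11 above and 3 below. Over the HCC 86.84% lay outside, against 32.5% in a normal liver left out in turn. These values restate the pattern that prompted the test, so they give no separate verdict on mixing. The test was set aside after its value was seen and then restored. A difference tied to Y-linked signal that normal liver shares is argued against by 0.1188 among normal livers and 3.04 among HCC. A tumour-specific difference in the activity of the pathway may remain as a hypothesis, and no mutation was measured here.

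The mean difference with Y-linked signal was smaller in HCC than in normal liver for male- and female-biased genes, though neither list passed adjustment over 40 lists (adjusted p = 0.159 and 0.0635, exact permutation). A lower share of hepatocytes is argued against only as far as the complement and coagulation list measures that share. In each of the 4 HCC with Y-linked signal the male-biased list lay further below normal than that list, by at least 2.284. Hepatocyte lists did not fall alike, since the cytochrome P450 list lay between -2.01 and -1.80 in these 4 HCC relative to all normal livers. Against that list the explanation was not tested. Compression of low values could remain: 10 brighter male-biased members had a median loss of 1.188, with a range from -1.32 to 5.93. These members were also chosen for a large difference among the same normal livers, which favours a loss. The HCC means of Elovl3 and Cyp4a12a, 6.95 and 6.78, were barely above the median probe set at 6.76, and their losses were 5.49 and 5.93. Limma's interaction of group and Y-linked signal passed for 28 genes, with 1570 at an unadjusted p under 0.05. The tumours without Y-linked signal, HCC 1 and HCC 4, were also those with the highest Wnt target and lowest periportal means. Where an interaction comes from the HCC, it cannot be told apart from that difference between tumours. Examples chosen after their values were seen were Elovl3 at -5.49, Slco1a1 at -7.39, Hsd3b5 at -8.95 and Sult3a1 at 6.26. In these genes the difference with Y-linked signal lay mainly among normal livers. It was 5.53 there and 0.04 in HCC for Elovl3, and 6.98 and -0.41 for Slco1a1. For Hsd3b5 it was 7.39 and -1.56, and for Sult3a1 -7.92 and -1.67. Others, such as Rhbg at 0.52 and -4.18, differed mainly among HCC.

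Genes on chromosome 4 had a median below normal liver in 6 of 6 HCC, with a mean of -0.171 ± 0.125 (SD, n = 6, exact permutation p = 0.00216, adjusted over 20 chromosomes 0.0144). In HCC 5, at -0.0227, 51.9% of chromosome 4 genes lay below normal, against 52.2% on other autosomes. Of the 20 chromosomes 9 passed: 4, 8, 13, 9, 14, 17 and 19 lower, and 15 and X higher. The medians were not centred on the shift over all brighter genes, a median of -0.039. Chromosomes 14 and 17, with differences of -0.054 and -0.059, lay close to that shift. Normalization that depends on intensity is argued against, since 5 of 6 tumours lay below nearly all of 10000 random gene sets of like level, although HCC 3, at -0.0917, was at the bound of -0.0898. A few strongly regulated gene clusters are argued against as the whole cause in 3 HCC, where the share of chromosome 4 genes below normal exceeded that of other autosomes by 14.1 ± 1.83 (HCC 1), 12.1 ± 1.83 (HCC 4) and 14.8 ± 1.77 (HCC 6) points (SE over 688 genes taken as independent). Loss of copies in part of the tumour cells stays open. Its test decides nothing, since it used HCC 6, chosen for the lowest median, where the highest of 4 stretches of genes was at -0.2111. In HCC 4 the stretches, in chromosome order, were at -0.731, -0.416, 0.03 and -0.07, so its fall was not even along the chromosome.

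Among list means, the cytochrome P450 list was at -0.2186 in normal 2, with the other normal livers between 0.0138 and 0.0740. The glycolysis list was at -0.3175 in normal 4 and at 1.47 in HCC 6. The extracellular matrix list was at 3.145 and the T and NK cell list at 1.228 in HCC 6, where the highest other HCC were at 0.612 and 0.434.

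Single arrays stood apart in these log2 levels. HCC 5 had Mup10 at 7.465, Ube2c at 7.92 and Cdk1 at 7.238, HCC 6 had G6pc at 12.55, and HCC 2 had Cidec at 9.613. Normal 1 had Mup3 at 12.11, Lpl at 12.05 and Hlf at 11.23, and normal 3 had Hsd17b7 at 11.86. Normal 4 had Cd14 at 7.285 and Glul at 13.29, and normal 5 had Asns at 5.592 and Phgdh at 8.966. Normal 6 had Dct at 9.329, Esm1 at 8.842 and Fabp4 at 11.09.

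Among the 10092 probe sets without a single gene name, 325 were higher and 209 lower in HCC.

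In 100 splits of the 12 arrays into 6 and 6, only the real one (1 of 100) gave as many genes in either direction, with 1179 and 1319 genes against a highest other of 2. Chance is therefore an unlikely source of these counts, though only 100 of the 462 possible splits were run. A batch that follows the groups was not tested, since the labels give none. For gene lists, 32 of 100 splits, the real one included, gave at least as many in either direction, with 11 higher and 11 lower lists against a highest other of 18, so chance cannot be excluded for the number of lists.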

How the results depend on the processing

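The deposited scaling, median centring, the Y-linked covariate, the restrictions by Y-linked signal and the exact permutation of list means were chosen after the data were seen. Genes higher in HCC numbered 575 in the arrays with Y-linked signal, 40 in those without it, 517 at an adjusted p under 0.01 and 1971 over every probe set. Genes lower numbered 564, 36 and 462 under the first 3 of these, and 838 with a replicate block, where 861 were higher and 64.8% of the calls were kept. Fewer arrays, a stricter threshold and more features tested enter by construction. So do the extra terms that a replicate block adds to the fit, and whether anything else enters there was not tested. Leaving out each array in turn gave 893 to 1220 genes higher and 919 to 1444 lower, 10 to 13 lists higher and 10 to 12 lower, and a difference in spread of 0.0912 to 0.131.

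Lists higher numbered 18 in the arrays with Y-linked signal and 1 with an estimated correlation, and lists lower 2 with an estimated correlation. In the arrays without Y-linked signal, 2 HCC and 2 normal livers, 10 of 40 list means changed sign, among them Wnt targets to 1.877, female-biased genes to -1.499 and extracellular matrix to -0.1575. With the mean of all probe sets of a gene, 28 of 2498 called genes changed sign. The difference in spread kept its direction under every alternative run. Between 14.2% and 18.1% of probe sets lay under an intensity of 16, where differences are compressed by the pseudocount.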

Other observations

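Igf2, chosen after its values were seen, encodes a fetal growth factor and is imprinted. It was at a mean log2 level of 10.41 ± 3.51 in HCC and 7.51 ± 0.39 in normal liver (SD, n = 6 each), a difference of 2.90 that did not pass (limma adjusted p = 0.157). The imprinted list mean was 0.46 in HCC 1, -0.13 in HCC 2, 0.56 in HCC 3, 1.21 in HCC 4, -0.30 in HCC 5 and 0.75 in HCC 6 relative to normal liver.

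The interferon response list mean was 2.19 in HCC 6 and between 0.18 and 1.02 in the other HCC. The first principal component over all genes held 32.2% of the variance.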
